A study of Mus musculus with 16 samples.

How the data were processed

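Gene expression was measured by RNA sequencing in 16 samples of native megakaryocytes, 4 each of Mpig6b mutant females, wild-type females, mutant males and wild-type males. Per the labels, cells were separated from bone marrow with anti-CD61 magnetic beads, RNA was taken with TRIzol and RNeasy columns, 50 ng of total RNA went into stranded poly(A) libraries, and these were sequenced on a NextSeq 500 with single 75 nt reads. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, cutadapt 2.1, STAR 2.7.2b, featureCounts 1.6.4 and DESeq2 1.24.0 with genome build GRCm38.p6, and the notes give no order or parameters for them.

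The values used were the authors' gene-level counts in 1 table, deposited with fractions and handled here in the unit of an expected count. The deposited values were not normalised, and how the fractions arose is not stated, although the commonest ones are simple fractions, such as reads split between genes would give. Of the non-zero values 34.8% were whole numbers within 1e-06. The plan written beforehand had assumed whole counts, so the expected counts were rounded, which changed the total of a library by at most 0.0028%. Totals ran from 22948523 to 31594513 counts per library, so a gene with a count of 3 over 4 libraries lies at about 0.0278 CPM. The table held 39331 genes, of which 6740 had no count in any library. Genes that overlap on the genome, close paralogs and antisense pairs share counts in such a table, and the largest overlapping partner of each named gene was looked up from the table's coordinates.

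Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr by group, which left 18037 genes, and libraries were scaled by TMM. A quasi-likelihood model with 4 group means was fitted to all 16 samples, with a biological coefficient of variation of 0.165. The contrasts were the genotype effect averaged over sexes, within females and within males, the interaction of genotype and sex, and the sex effect in wild type and in mutants. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and standard errors of log2 fold changes come from the same model. Of the 18037 genes, those with a log2 fold change beyond 1 in either direction were also counted.

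The 30 gene lists were fixed before the data were examined. They covered megakaryocyte transcription factors, surface receptors, granules and cytoskeleton, thrombopoietin and JAK-STAT signalling, ITIM and Src family signalling, heparan sulphate proteoglycans, S phase, mitosis, stem cells, 9 other marrow cell types, extracellular matrix, inflammatory and interferon responses, cholesterol and fatty acid synthesis, stress responses, p53, glycolysis, ribosomal proteins, oxidative phosphorylation, the mitochondrial genome, and sex-linked genes. Each was tested in 4 comparisons with camera on limma-voom values (limma 3.58.1) at a preset correlation of 0.01, with the correlation estimated from the data beside it, and with fry, adjusted over the 30 lists. Camera asks whether the members of a list move more than other genes, while fry asks whether they move on balance in one direction and does not compare them with other genes. The share of counts of each list was compared with a 2-sided exact permutation test of 4 against 4 libraries.

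Genes named in the text were chosen by a rule written beforehand. These were Mpig6b, the 12 largest increases and 12 largest decreases that separated all mutant from all wild-type libraries with a mean log2 CPM of at least 2, up to 4 members of each list with the smallest p in the averaged comparison, of which the text names 2 to 4, the 5 largest differences in each direction for each sex effect, and 6 genes with the smallest p for the interaction. Other genes were named as labels of the sorting marker, sex or the lists. Predicted genes were counted but not named, apart from overlap partners.

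Alternatives, chosen before the data were examined, were DESeq2 size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom with sample quality weights, leaving out the 20 genes with most counts, leaving out each library in turn, a block for the replicate number, only the 2 groups compared, an additive model and genotype alone. The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. edgeR found 93 and 98% of these in the averaged comparison, 75 and 96% in females, 76 and 93% in males, 60 and 88% for the interaction, 87 and 99% for the sex effect in wild type and 73 and 97% for that in mutants, and between 4 and 11 unchanged genes were called. DESeq2 found 92 and 99% and limma-voom 93 and 98% in the averaged comparison. Camera called the changed list in all 4 comparisons, and called 2 unchanged lists in males, while fry called the changed list in all 4 comparisons and 1 unchanged list in the averaged comparison and 3 in males. The simulated genes varied independently, the changed ones were few, and as many rose as fell. In the real data 67.4% of genes were called in the averaged comparison. These rates therefore do not cover scaling errors or list tests under such conditions. The labels of the libraries were also permuted to see how many genes and lists other splits of the same libraries call. Reads were not analysed here.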

Results

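RNA sequencing was used to compare native megakaryocytes, the platelet-producing cells of the bone marrow, from untreated C57BL/6 mice that were wild type or mutant for Mpig6b. The cells were taken from bone marrow by magnetic separation with an antibody against CD61, the integrin subunit encoded by Itgb3. Mpig6b encodes G6b-B, an inhibitory receptor of megakaryocytes and platelets that carries immunoreceptor tyrosine-based inhibition motifs (ITIM). The series title names loss of this receptor together with thrombopoietin signalling and differentiation of the megakaryocyte lineage. The 16 libraries formed 4 groups of 4, which were mutant females, wild-type females, mutant males and wild-type males. The deposited values were gene-level counts with fractions, and the totals per library ran from 22948523 to 31594513 counts. After rounding and a filter on low counts, 18037 genes were tested. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

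Mpig6b (GeneID 106722; GRCm38.p6, chromosome 17, 35062693 to 35066848, minus strand) was low in every mutant library. The 4 mutant female libraries had 1.88, 1.83, 3.86 and 1.78 CPM (counts scaled to library size). The 4 wild-type female libraries had 277, 211, 701 and 504 CPM. The mutant male libraries had 4.02, 4.16, 3.62 and 5.31 CPM, against 98.5, 107, 67.8 and 93.5 CPM in the wild-type males. The log2 fold change of Mpig6b was -7.49 ± 0.421 (SE, n = 4 per group) in females and -4.42 ± 0.367 in males, with adjusted p = 1.35e-07 and 2.23e-07 in edgeR's quasi-likelihood test. Set against Itga2b, which encodes the platelet integrin subunit CD41, Mpig6b was at 0.721 to 1.25% of the Itga2b level in the mutant libraries and at 7.6 to 11.5% in the wild-type libraries. The antisense gene G6bos lies within the Mpig6b locus and had low counts beside it. The sex labels held in every library, since Xist was at 309 to 367 CPM in the 8 female libraries and at 0.099 to 0.67 CPM in the 8 male libraries. Ddx3y, a Y-linked helicase gene, was at 130 to 173 CPM in males and at 3.45 to 4.66 CPM in females.

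**Figure D1:**
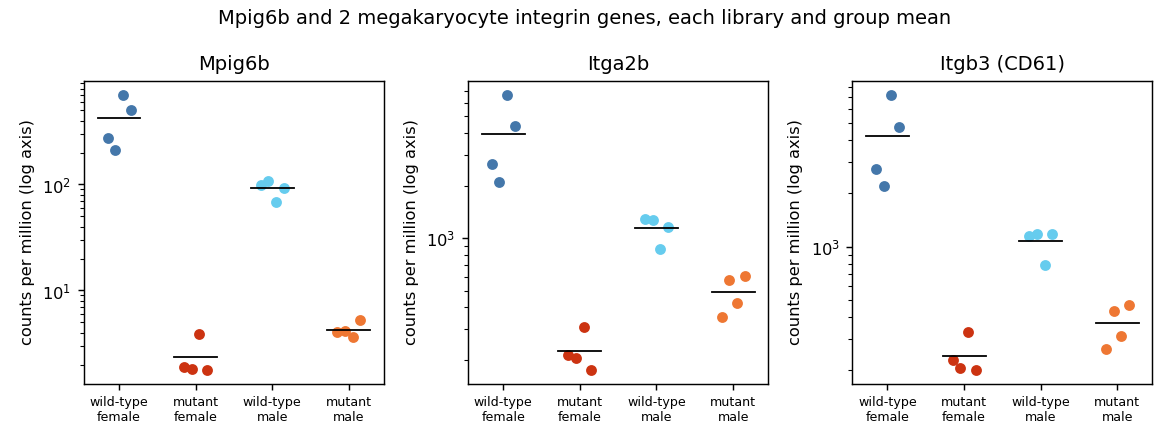
CPM of Mpig6b, Itga2b and Itgb3 in each of the 16 libraries, on log axes, with the group means as horizontal lines. All 8 mutant libraries lie below all 8 wild-type libraries for each of the 3 genes, and Mpig6b is between 1.78 and 5.31 in the mutants.

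The libraries differed in their content of transcripts from megakaryocytes and from other marrow cells. Genes for megakaryocyte and platelet surface receptors held 2.09 ± 0.92% of the counts (SD, n = 4) in wild-type females, 0.686 ± 0.096% in wild-type males, 0.233 ± 0.03% in mutant females and 0.292 ± 0.044% in mutant males. Genes of neutrophils and granulocytic precursors held 10.8 ± 0.52% in mutant females against 4.99 ± 2.1% in wild-type females, and 12.2 ± 0.5% in mutant males against 7.46 ± 0.94% in wild-type males. Genes of monocytes and macrophages held 2.72 ± 0.3% in wild-type males and between 1.17 and 1.43% in the other groups on average. The share of endothelial genes was 0.418 ± 0.18% in wild-type females, 0.156 ± 0.023% in wild-type males, 0.0472 ± 0.0073% in mutant females and 0.0646 ± 0.013% in mutant males. In a 2-sided exact permutation test the receptor, neutrophil, erythroid and endothelial shares differed by genotype within each sex (n = 4 per group, p = 0.0286, the smallest this design allows). Adjusted over the 30 lists, these p-values were 0.0452 in females and 0.0409 in males. Wild-type female replicate 3 stood apart from its group, with 3.31% of its counts in receptor genes, 2% in neutrophil genes and Itgb3 at 7223 CPM, against at most 4724 CPM in the other wild-type libraries.

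**Figure D2:**
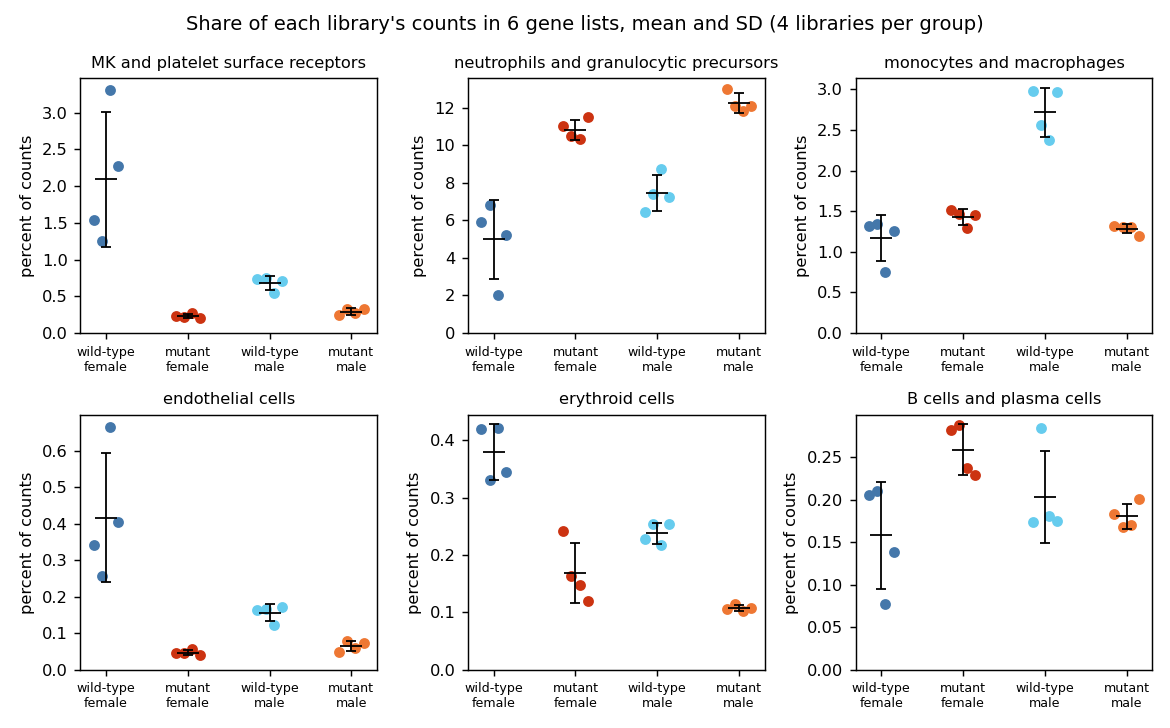
Percent of each library's counts in 6 gene lists (points), with the mean and SD of the 4 libraries of each group. Receptor and endothelial shares are lower and neutrophil shares higher in the mutant groups, while the macrophage share of wild-type males, 2.72%, lies above those of the other 3 groups.

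The genotype comparison averaged over the sexes addressed which transcripts differ when Mpig6b is mutated. Surface receptor genes of the mature megakaryocyte were lower in the mutants. Member counts of lists are to be read against the share of all 18037 tested genes called. This was 67.4% in the averaged comparison (5484 genes higher and 6677 lower), 65.5% in females and 42.7% in males. For the interaction it was 27%, and for the sex effects 46.1% in wild type and 25% in mutants. All 34 tested genes of the list of megakaryocyte and platelet surface receptors were lower (34 adjusted over the list alone), with a median log2 fold change of -2.63. They included Gp6, the platelet collagen receptor, at -4.13 ± 0.280 (SE, n = 8 mutant and 8 wild-type libraries) and Gp9, a subunit of the von Willebrand factor receptor, at -3.59 ± 0.246. Clec1b, the podoplanin receptor, was at -3.28 ± 0.209 and the ADP receptor gene P2ry12 at -2.73 ± 0.188. Both overlap genes with larger counts (Clec12b and Med12l), so their counts are uncertain. Among granule genes 28 of 43 were lower and 10 higher (29 and 10 adjusted over the list alone), with the insulin-like growth factor gene Igf1 at -3.91 ± 0.155, the chemokine gene Ppbp at -4.51 ± 0.283 and the growth factor gene Pdgfa at -3.01 ± 0.217. Unlike Ppbp, Igf1 was higher in wild-type males (114.8 CPM) than in wild-type females (39.08 CPM) and lowest in mutant males (2.253 CPM), as macrophage genes were. Of 50 genes of the proplatelet and actin-tubulin cytoskeleton, 31 were lower and 6 higher (31 and 6 over the list alone), led by Myl9 at -4.32 ± 0.242, the platelet tubulin Tubb1 at -4.11 ± 0.260 and Parvb at -3.77 ± 0.239. The 25 megakaryocyte transcription factor genes had 13 lower and 8 higher (13 and 8 over the list alone), with Gfi1b at -1.91 ± 0.177, Tal1 at -2.01 ± 0.190 and Gata2 at -1.24 ± 0.107. Gata1, at -2.27 ± 0.194, overlaps the predicted gene Gm39488 with about as many counts. Camera with a preset correlation called the receptor (adjusted p = 6.33e-14), granule (0.00424) and cytoskeleton (0.00021) lists lower and not the transcription factor list (0.402). With an estimated correlation no list passed, with adjusted p = 0.582 for the first 3 and adjusted p = 0.764 for the transcription factors. The granule and cytoskeleton lists were called in females and not in males.

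Signalling lists close to the G6b-B receptor held members that moved in both directions in the averaged comparison. Tested genes as a whole did so too, with 67.4% of them called, so this is not particular to these lists. Of 48 genes of thrombopoietin and JAK-STAT signalling, 21 were higher and 16 lower (21 and 18 adjusted over the list alone). The thrombopoietin receptor gene Mpl was at -2.61 ± 0.218, Hes1 at -2.75 ± 0.181 and Spry1, an inhibitor of receptor tyrosine kinase signalling, at -1.68 ± 0.174. The median of this list was 0.09 and its mean -0.18, and camera placed it up (adjusted p = 0.502) while fry placed it down (adjusted p = 0.254). Of 46 genes of ITIM, ITAM and Src family signalling, 21 were lower and 14 higher (21 and 14 over the list alone), among them Mpig6b itself and the exchange factor gene Vav2 at -1.85 ± 0.106, with adjusted p = 0.125 in camera and adjusted p = 0.582 with an estimated correlation. Of 32 genes of heparan sulphate proteoglycans and their synthesis, a class of ligands of G6b-B, 21 were lower and 6 higher (21 and 6 over the list alone). Sdc3, a syndecan, was at -3.41 ± 0.152, and Hpse, the heparanase gene, was at -2.35 ± 0.174. Hpse followed the megakaryocyte gene Itga2b, with 403.2 and 140.3 CPM in wild-type female replicates 3 and 2, where Itga2b was at 6659 and 2114 CPM. Sdc3 and Vav2 followed the groups as the macrophage genes Axl and Mrc1 did, with Sdc3 at 589.5 CPM in wild-type males, 179.1 CPM in wild-type females and 15.01 CPM in mutant males on average, so these falls went with those of macrophage markers. Camera called that list lower at adjusted p = 0.00846, with adjusted p = 0.582 with an estimated correlation.

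Marker genes of other marrow cells also differed by genotype. Of 41 neutrophil and granulocyte genes, 36 were higher and none was lower (36 adjusted over the list alone), with a median of 1.03. The chemokine receptor gene Cxcr2 was at 1.30 ± 0.178, the gelatinase gene Mmp9 at 1.19 ± 0.138 and the leukotriene receptor gene Ltb4r1 at 0.60 ± 0.064. Of 47 monocyte and macrophage genes 32 were lower and 9 higher (32 and 9 over the list alone), and Mrc1, the mannose receptor of tissue macrophages, was at -4.20 ± 0.157. The haem oxygenase gene Hmox1 was at -3.55 ± 0.136 and Vcam1 at -3.07 ± 0.122. Of 49 erythroid genes 42 were lower and 3 higher (42 and 3 over the list alone). Among the lower ones were Snca, which encodes alpha-synuclein, at -3.75 ± 0.255 and Tmcc2 at -2.80 ± 0.145. Snca followed the megakaryocyte gene Itga2b, with 257.2 and 80.57 CPM in wild-type female replicates 3 and 2. Itga2b was at 6659 and 2114 CPM there, so the fall of Snca went with those of megakaryocyte genes. Of 35 endothelial genes 31 were lower and 2 higher (31 and 2 over the list alone), including the sinusoidal scavenger receptor gene Stab2 at -3.95 ± 0.196 and Fabp4 at -4.29 ± 0.269. The endothelial list held 4 genes that are also in a megakaryocyte list, and of its 28 genes in no other list 25 were lower. Of 40 stromal and osteoblastic genes 22 were lower and 3 higher (22 and 3 over the list alone). Among the lower ones were the lipoprotein lipase gene Lpl at -3.37 ± 0.193 and the adiponectin gene Adipoq at -3.06 ± 0.266. Unlike Adipoq, Lpl was highest in wild-type males (246 to 464.2 CPM) and lowest in mutant males (9.393 to 20.04 CPM), as macrophage genes were. Camera with a preset correlation called the neutrophil list higher (adjusted p = 5.92e-10) and the macrophage (6.7e-07), erythroid (2.41e-08), endothelial (6.69e-09) and stromal (0.00263) lists lower, and each had adjusted p = 0.582 with an estimated correlation.

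Lymphoid, basophil and osteoclast lists had smaller differences in the averaged comparison. Of 40 B cell and plasma cell genes 8 were lower and 3 higher (7 and 3 adjusted over the list alone), with Cd37, a tetraspanin gene, at 0.75 ± 0.104 and the B cell receptor subunit gene Cd79b at -0.91 ± 0.127. Cd37 was at 87.23 CPM in wild-type female replicate 3, which had the lowest neutrophil share (2%). The other wild-type females had 144.1 to 170.9 CPM, so its rise went with those of neutrophil genes. In males Cd79b was at 6.738 to 8.685 CPM in mutants against 29.79 to 41.27 CPM in wild type. In females its ranges overlapped, at 22.48 to 42.72 CPM in mutants and 21.09 to 30.09 CPM in wild type. The list's median was 0.12 and its mean 0, with adjusted p = 0.62 in camera and adjusted p = 0.906 with an estimated correlation. Of 42 T and NK cell genes 7 were higher and 5 lower (4 and 4 over the list alone), with adjusted p = 0.089 in camera and adjusted p = 0.764 with an estimated correlation. Among its lower members were Lat, at -2.03 ± 0.227, an adaptor that platelets also use, and the co-receptor gene Cd4 at -1.79 ± 0.217. In males Cd4 was at 4.322 to 7.216 CPM in mutants against 49.38 to 80.35 CPM in wild type. In females its ranges overlapped, at 17.11 to 37.32 CPM in mutants and 13.44 to 42.4 CPM in wild type. Of 37 genes of basophils, mast cells and eosinophils 17 were higher and 5 lower (17 and 5 over the list alone), with adjusted p = 0.0138 in camera and adjusted p = 0.582 with an estimated correlation. Its lower members included the eotaxin receptor gene Ccr3 at -1.77 ± 0.154 and Itga2b at -2.68 ± 0.228, one of 5 genes it shares with megakaryocyte lists. Like macrophage genes, Ccr3 and Cd4 were highest in wild-type males and lowest in mutant males, with Ccr3 at 187 to 303.2 and 20.61 to 33.59 CPM. Of 26 osteoclast genes 8 were lower and 4 higher (7 and 4 over the list alone), with adjusted p = 0.709 in camera and adjusted p = 0.906 with an estimated correlation, with the podosome scaffold gene Sh3pxd2a at -1.51 ± 0.125 and the osteoclast regulator gene Nfatc1 at 0.40 ± 0.046.

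Mitosis genes were slightly higher in the averaged comparison. Of 63 genes of G2-M and mitosis 58 were higher and 1, Pttg1 at -0.45 ± 0.067, was lower (58 and 1 adjusted over the list alone), with a median of 0.33. Cks2, a partner of cyclin-dependent kinases, was at 0.67 ± 0.102 and Spc25, a kinetochore gene, at 0.49 ± 0.082. Of 54 genes of S phase and replication 25 were higher and none was lower, while 29 did not pass (19 and 0 over the list alone), with a median of 0.18, E2f2 at 0.87 ± 0.155 and the clamp loader gene Rfc2 at 0.23 ± 0.033. Wild-type female replicate 3, with the lowest neutrophil share (2%), had E2f2 at 48.56 and Cks2 at 45.49 CPM. The other wild-type females had 112 to 144.6 and 75.68 to 87.6 CPM, so these rises went with those of neutrophil genes. Rfc2 differed little there (66.65 against 68.59 to 71.16 CPM). Of 45 stem and progenitor cell genes 29 were lower and 10 higher (29 and 10 over the list alone), with Slamf1 at -4.07 ± 0.246, Gcnt2 at 0.82 ± 0.062 and Mmrn1, a granule protein gene also in the granule list, at -3.25 ± 0.253. This list shared 9 of its tested genes with the megakaryocyte lists. Slamf1 is not among these, but it followed Itga2b, with 539.3 and 164.3 CPM in wild-type female replicates 3 and 2. Itga2b was at 6659 and 2114 CPM there. Camera with a preset correlation called the mitosis (adjusted p = 2.19e-08) and S phase (0.000347) lists higher and the stem cell list lower (0.00263), each with adjusted p = 0.582 with an estimated correlation. In males 8 of the 63 mitosis genes and 3 of the 54 S phase genes were higher. Camera called the mitosis list higher in males as well (adjusted p = 0.000476, and adjusted p = 0.947 with an estimated correlation) and not the S phase list (0.199, and 0.95). The interaction was called for 4 of the 63 mitosis genes, 3 positive and 1 negative, and 6 of the 54 S phase genes, so for most of them a difference between the sexes was not shown. In males the shares of counts were 0.591% in mutants and 0.596% in wild type for mitosis genes and 0.269 and 0.285% for S phase genes.

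Matrix, inflammatory and metabolic lists completed the averaged comparison. Of 62 genes of the extracellular matrix and of mediators of myelofibrosis 36 were lower and 12 higher (36 and 12 adjusted over the list alone), with the growth factor genes Pdgfc at -3.74 ± 0.214 and Bmp2 at -3.47 ± 0.220. Pdgfc had its highest level in wild-type males and its lowest in mutant males, as macrophage genes did. The same held for Il18 and Gdf15, which are named below with other lists. Il18 was at 40.37 to 63.88 CPM in wild-type males and 4.007 to 4.628 CPM in mutant males. Gdf15 was at 164.5 to 306.1 and 2.927 to 6.072 CPM. Camera gave adjusted p = 0.0138 for the matrix list, and adjusted p = 0.582 with an estimated correlation. The share of counts of this list was nevertheless higher in the mutants, at 5.6 against 3.49% in females and 6.3 against 4.1% in males (exact permutation test, p = 0.0286 in each sex). The list shares 25 of its tested genes with other lists, among them the neutrophil gene Mmp9. Of its 37 genes in no other list 24 were lower and 4 higher, with a median of -0.81, so the higher share does not describe most members. Of 54 inflammatory and NF-kB genes 37 were higher and 11 lower (37 and 11 over the list alone, camera's adjusted p = 0.00149, and adjusted p = 0.582 with an estimated correlation), although the 4 members with the smallest p were all lower and included Il18, an interleukin gene, at -2.31 ± 0.127 and the early response gene Egr1 at -0.75 ± 0.079. Of 59 interferon response genes 24 were higher and 11 lower (23 and 11 over the list alone, camera's adjusted p = 0.0625, and adjusted p = 0.764 with an estimated correlation), and the immunity-related GTPase genes Igtp, at -2.91 ± 0.180, and Ifi47, at -2.18 ± 0.172, were among the lower ones. Cholesterol and fatty acid genes were split, with 13 higher and 12 lower of 38 (13 and 12 over the list alone). Their median was -0.02 while camera placed the list up (adjusted p = 0.605, and adjusted p = 0.866 with an estimated correlation) and fry down. With DESeq2 size factors the median was 0.02. Among the lower genes, the cholesterol synthesis gene Dhcr24 was at -2.64 ± 0.205 and the lipin gene Lpin1 at -1.26 ± 0.113. Dhcr24 and Igtp followed Itga2b, with 528.5 and 665.3 CPM in wild-type female replicate 3 and 188.7 and 237 CPM in replicate 2. Itga2b was at 6659 and 2114 CPM in these libraries. Ifi47, Bmp2 and, named below, Bcl2l1 also followed it among wild-type females. They were at 316.8, 72.02 and 267.2 CPM in replicate 3 and at 115.9, 25.24 and 111.4 CPM in replicate 2. Of 43 genes of the unfolded protein and integrated stress responses 23 were lower and 10 higher (23 and 11 over the list alone, camera's adjusted p = 0.0997, and adjusted p = 0.582 with an estimated correlation), with the stress cytokine gene Gdf15 at -3.53 ± 0.205 and the asparagine synthetase gene Asns at 0.59 ± 0.076. Of 42 p53 and apoptosis genes 22 were higher and 12 lower (23 and 15 over the list alone, camera's adjusted p = 0.0847, and adjusted p = 0.582 with an estimated correlation), with Trp53inp1 at 0.93 ± 0.091 and the survival gene Bcl2l1 at -1.30 ± 0.145. Of 40 glycolysis and hypoxia genes 21 were higher and 10 lower (21 and 10 over the list alone, camera's adjusted p = 0.0657, and adjusted p = 0.582 with an estimated correlation), with Ddit4 at 0.93 ± 0.074 and the collagen hydroxylase gene P4ha1 at -1.21 ± 0.097.

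Transcripts of the mitochondrial genome were lower in the mutants. All 13 were lower (13 adjusted over the list alone), with a median of -0.73 and the cytochrome b gene CYTB at -0.80 ± 0.085 and ND1 at -0.69 ± 0.074. Of 85 genes of oxidative phosphorylation 45 were lower and 7 higher (45 and 7 over the list alone), with a median of -0.18, Atp5e at -1.49 ± 0.130 and Uqcrh at 0.71 ± 0.085. Atp5e went with the megakaryocyte gene Itga2b among wild-type females, with 288.5 and 128.4 CPM in replicates 3 and 2, where Itga2b was at 6659 and 2114 CPM. Of 84 genes for cytosolic ribosomal proteins 51 were lower and 5 higher (52 and 5 over the list alone), with a median of -0.13 with Rplp1 at -0.44 ± 0.042 and Rps2 at -0.32 ± 0.048. Of 10 tested Y-linked and X-inactivation genes 3 were higher and 1 lower (3 and 1 over the list alone), with a median of 0.10, a mean of -0.01, and the X-linked genes Ddx3x at 0.30 ± 0.054 and Kdm6a at 0.19 ± 0.038. Camera called the mitochondrially encoded (adjusted p = 4.37e-06), oxidative phosphorylation (0.0045) and ribosomal (0.000615) lists lower and not the Y-linked list (0.282). None passed with an estimated correlation, with adjusted p = 0.606 for the ribosomal list and adjusted p = 0.582 for the other 3.

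Among genes that separated all mutant from all wild-type libraries, the 12 largest increases included the glutathione-cycle enzyme gene Ggt1 at 1.86 ± 0.208, Ifitm1 at 1.68 ± 0.196, the cytokine gene Il1b at 1.38 ± 0.189, the antiviral synthetase gene Oas3 at 1.36 ± 0.239, the Schlafen genes Slfn4 at 1.35 ± 0.213 and Slfn1 at 1.32 ± 0.174, Rdh12 at 1.35 ± 0.178, Cxcr2, Crispld2 at 1.28 ± 0.182 and Gpat3 at 1.27 ± 0.179. The other 2, Il1bos and Trim30b, overlap Il1b and the predicted gene Gm38525, which have more counts, so their values are uncertain. Schlafen genes are close paralogs, which also makes their counts uncertain. The genes of the 12 largest increases had their lowest level in wild-type female replicate 3, which also had the lowest neutrophil share (2%). Il1b and Slfn4 were at 255.6 and 208.3 CPM there. The other wild-type females had 838.1 to 901.1 and 786.6 to 846.4 CPM, so these rises went with those of neutrophil genes. The 12 largest decreases included genes of tissue macrophages, with the lectin genes Cd209g at -6.22 ± 0.293 and Cd209f at -6.11 ± 0.235, the scavenger receptor gene Marco at -5.49 ± 0.391, Cd5l at -5.18 ± 0.266 and the phosphatidylserine receptor gene Timd4 at -4.95 ± 0.246. The fitted folds of Cd209g, Cd209f, Marco and Btnl6 rested on 4, 16, 6 and 9 counts summed over the mutant males, and those of Rnf165 and Aldob on 21 and 22 counts there and 22 each in mutant females. The remaining decreases were Mpig6b, its antisense neighbour G6bos, Btnl6 at -5.27 ± 0.263, Rnf165 at -5.03 ± 0.303, Gfra2 at -4.93 ± 0.242, Gpd1 at -4.88 ± 0.205, which overlaps Gm16537, and Aldob at -4.84 ± 0.372. In all, edgeR called 12161 of 18037 genes at an adjusted p below 0.05, of which 5484 were higher and 6677 lower, and 531 higher and 2663 lower genes changed at least 2-fold. Of the tested genes, 1924 were higher in every mutant library than in every wild-type library, and 2383 were lower.

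**Figure D3:**
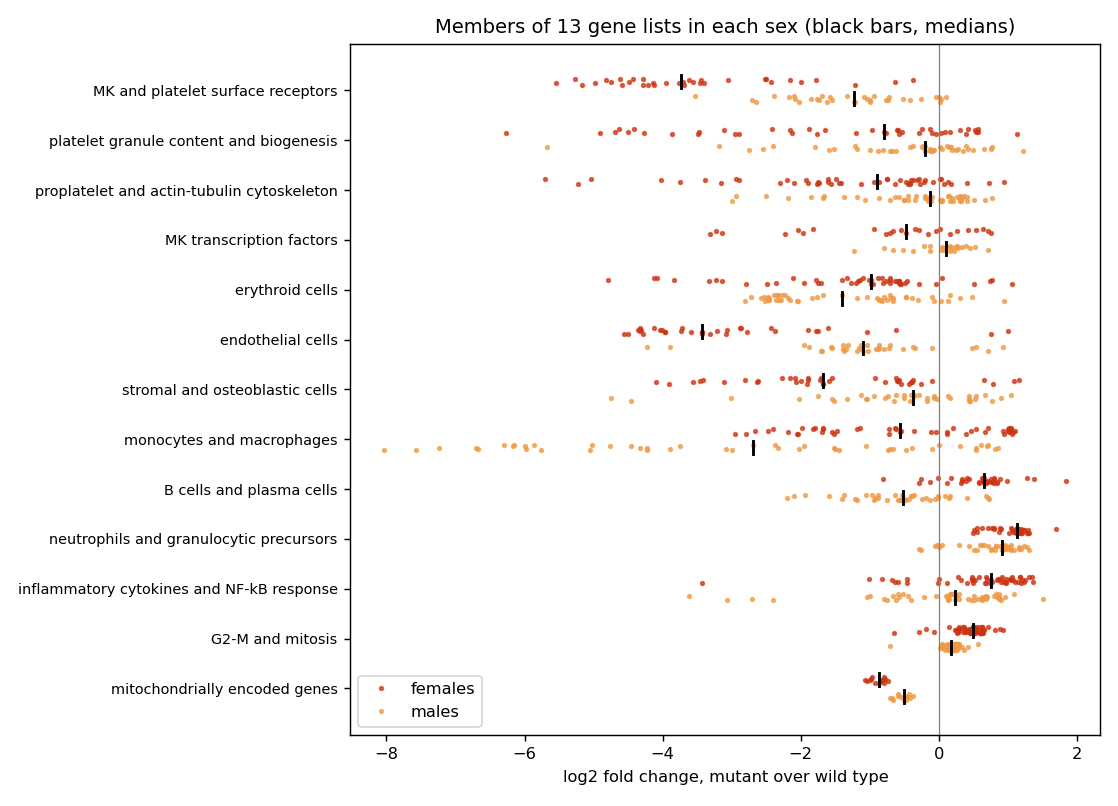
Log2 fold change of mutant over wild type for each tested member of 13 gene lists, in females (red) and males (orange), with medians as black bars. The receptor list has medians of -3.74 in females and -1.22 in males, the macrophage list -0.56 and -2.69, and the neutrophil list 1.13 and 0.91.

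Within females, the genotype comparison had its largest list difference in megakaryocyte genes. All 34 receptor genes were lower, with a median of -3.74 (34 adjusted over the list alone), and Ppbp was at -6.27 ± 0.436 (SE, n = 4 per group), Gp9 at -5.17 ± 0.374 and Mpl at -4.22 ± 0.332. Of 50 cytoskeleton genes 41 were lower and 4 higher (41 and 4 over the list alone), and of 25 megakaryocyte transcription factor genes 16 were lower and 7 higher (16 and 7 over the list alone), with Gfi1b at -3.15 ± 0.261 and Tal1 at -3.22 ± 0.282. Of 35 endothelial genes 33 were lower and 2 higher (33 and 2 over the list alone). Of 41 neutrophil genes 38 were higher and none was lower (39 over the list alone), of 54 inflammatory genes 39 were higher and 6 lower (41 and 6 over the list alone), and of 63 mitosis genes 58 were higher and 2 lower (58 and 2 over the list alone). Of 40 B cell genes 15 were higher and 2 lower, and of 42 T and NK cell genes 21 were higher and 2 lower (13 and 1, and 21 and 2, over the list alone), while 23 and 19 did not pass. The share of T and NK cell genes was 0.0309% in mutant and 0.0345% in wild-type females (exact permutation test, p = 0.429). Of 47 macrophage genes 24 were lower and 12 higher (24 and 12 over the list alone), and their share of counts was 1.43% in mutant and 1.17% in wild-type females (p = 0.0857 in the exact permutation test). These differences went with a receptor share of 0.233% against 2.09% and a neutrophil share of 10.8% against 4.99%. Camera called 23 of 30 lists, 8 higher and 15 lower, and none passed with an estimated correlation (adjusted p = 0.517 for the receptor, cytoskeleton, endothelial, neutrophil, inflammatory, mitosis and transcription factor lists). edgeR called 11809 genes, 5498 higher and 6311 lower, of which 1143 and 3166 changed at least 2-fold. With the DESeq2 Wald test 6041 were higher and 6000 lower, so the excess of lower genes depended on the setting.

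Within males, the genotype comparison had its largest list difference in macrophage genes. Of 47 genes 33 were lower and 4 higher (33 and 6 adjusted over the list alone), with a median of -2.69, and Axl, a receptor tyrosine kinase gene of tissue macrophages, fell from 1108 to 15.5 CPM, a log2 fold change of -6.16 ± 0.279 (SE, n = 4 per group). Mrc1 was at -5.99 ± 0.241 and Hmox1 at -5.06 ± 0.207. Of 34 receptor genes 25 were lower and none was higher (26 over the list alone), with a median of -1.22, Gp6 at -2.71 ± 0.372 and Mpl at -1.001 ± 0.293. Of 49 erythroid genes 40 were lower and 2 higher (41 and 3 over the list alone), of 35 endothelial genes 23 were lower and 3 higher (23 and 3), and of 40 B cell genes 13 were lower and 2 higher (13 and 2), with Cd79b at -2.20 ± 0.188. Of 41 neutrophil genes 31 were higher and none was lower (32 over the list alone), and of 40 glycolysis and hypoxia genes 23 were higher and 5 lower (23 and 5). The shares of counts were 0.292% against 0.686% for receptor genes, 1.28% against 2.72% for macrophage genes and 12.2% against 7.46% for neutrophil genes. Camera called 11 of 30 lists, 3 higher and 8 lower, and none passed with an estimated correlation (adjusted p = 0.538 for the macrophage, erythroid and glycolysis lists, adjusted p = 0.859 for receptors and adjusted p = 0.873 for the neutrophil and endothelial lists). edgeR called 7694 genes, 3569 higher and 4125 lower, of which 306 and 1958 changed at least 2-fold. The excess of lower genes turned with DESeq2 size factors (3941 higher, 3831 lower), the DESeq2 Wald test (4180 and 4045), no filter on low counts (3765 and 3503) and without mutant male replicate 1 (3462 and 3147). Camera did not call 9 lists in males that it called in females and on average, which were the granule, cytoskeleton, S phase, stem cell, basophil, stromal, extracellular matrix, inflammatory and oxidative phosphorylation lists. Granule genes were 15 lower and 9 higher (camera's adjusted p = 0.337), cytoskeleton genes 16 lower and 13 higher (0.575) and inflammatory genes 19 higher and 11 lower (0.337). Leaving out mutant male replicate 1 ended the call of Mpl in males, with a log2 fold change of -0.82. Gfi1b was at -0.67 ± 0.243 in males and lost its call without a filter on low counts (-0.61), and without mutant male replicate 1, 3 or 4, wild-type male replicate 1, 2 or 4 or mutant female replicate 1, at -0.54 to -0.72. Tal1 was at -0.79 ± 0.261 and lost its call without mutant male replicate 1 or 3 or wild-type male replicate 1 or 2, at -0.63 to -0.74.

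The interaction of genotype and sex tested whether the genotype effect differed between the sexes, and megakaryocyte and macrophage genes differed in opposite directions. Of 34 receptor genes 33 had a more negative genotype effect in females (33 adjusted over the list alone), with a median difference of -2.56, and the difference was -3.22 ± 0.423 (SE) for Mpl and -2.84 ± 0.507 for Gp6. Of 47 macrophage genes 34 had a more negative effect in males and none in females (39 and 0 over the list alone), with a median difference of 2.17. Over all tested genes, the 6 with the smallest p were Lgmn (2.76 ± 0.208), Axl (4.34), Sdc3 (3.77 ± 0.287), Plxnb2 (1.96 ± 0.152), Slco2b1 (3.76 ± 0.293) and Vav2 (2.68 ± 0.209), each with adjusted p = 3.49e-06. Of these Lgmn and Axl are in the macrophage list, Sdc3 in the heparan sulphate list and Vav2 in the ITIM list. Of 50 cytoskeleton genes 39, and of 35 endothelial genes 26, had a more negative effect in females (39 and 26 over the list alone), although the difference did not pass for Stab2 (-0.12 ± 0.356, adjusted p = 0.833) and Fabp4 (-0.13 ± 0.490, adjusted p = 0.864). For B cell genes 18 of 40 differed, all with the higher effect in females (26 over the list alone). For the neutrophil list 1 of 41 genes differed. Camera called 19 of 30 lists, 7 positive and 12 negative, fry called 12, and none passed with an estimated correlation (adjusted p = 0.23 for the receptor, cytoskeleton and macrophage lists, adjusted p = 0.29 for the endothelial list and adjusted p = 0.468 for B cells). edgeR called 4875 genes, 1780 positive and 3095 negative. The receptor share differed most in the wild-type libraries, at 2.09% in females and 0.686% in males, and so did the macrophage share, at 1.17 and 2.72%.

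The within-sex comparisons shared no libraries, and 5900 genes were called in both. Of these 2763 were higher in both, 2870 lower in both and 267 changed in opposite directions, while independent lists of these sizes would share 1088 higher and 1443 lower genes. Across genes, which are not independent replicates, the log2 fold changes of the sexes had a Pearson r of 0.61 and a Spearman rho of 0.68. A further 5909 genes were called in females alone and 1794 in males alone, and the interaction was called for 2353 and 878 of these, so for the rest a difference between the sexes was not shown.

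**Figure D4:**
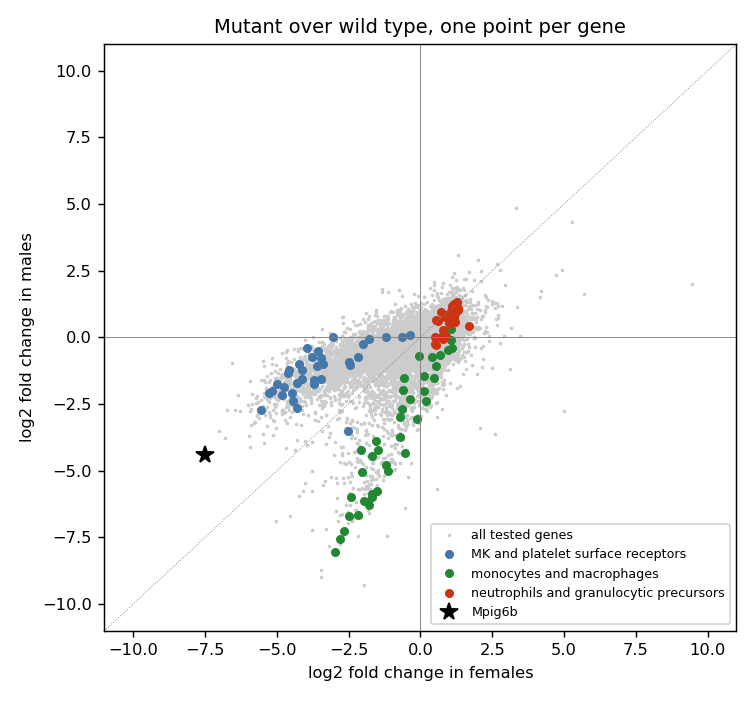
Log2 fold change of mutant over wild type in females (horizontal) and males (vertical), 1 point per tested gene, with 3 gene lists and Mpig6b marked and a dotted line of equal change. Receptor genes lie above the line and macrophage genes below it, where the change is more negative in females or in males, and neutrophil genes lie near it in the upper right.

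Among wild-type mice, females had higher levels of megakaryocyte genes and males of macrophage genes. Of 34 receptor genes 33 were higher in females and none in males (33 and 0 adjusted over the list alone), with Itga2b at 1.79 ± 0.312 (log2 of female over male, SE, n = 4 per group) and Ppbp at 1.98 ± 0.359. Endothelial genes went the same way (29 of 35 higher in females, none in males, 30 and 0 over the list alone). So did stromal genes (30 of 40 higher in females, 3 in males, 31 and 3 over the list alone). Of 40 B cell genes 19 were higher in females and 4 in males (19 and 6 over the list alone). Of 42 T and NK cell genes 17 were higher in females and 2 in males (20 and 2). Of 47 macrophage genes 35, and of 54 inflammatory genes 40, were higher in males and none in females (37 and 44 in males and 1 and 0 in females over the list alone), with Axl at -2.02 ± 0.230 and Mrc1 at -1.73 ± 0.198. The largest differences were those of sex-linked genes, with Xist at 10.49 ± 0.348 and the Y-linked genes Eif2s3y at -9.70 ± 0.389, Kdm5d at -7.83 ± 0.280, Uty at -7.70 ± 0.277 and Ddx3y at -5.16 ± 0.090. Tsix is antisense to Xist and its summed counts were close to those of Xist, 35692 and 35676 in wild-type females, so its value is uncertain. Next came Cthrc1 at 3.94 ± 0.594, Peg3 at 3.82 ± 0.503 and the cartilage collagen gene Col2a1 at 3.64 ± 0.444 in females, and towards males BC018473 at -4.16 ± 0.755. These folds rest on few counts for BC018473 (1 summed over the wild-type females and 28 over the males) and for Cthrc1 and Peg3 (27 and 13 over the wild-type males). edgeR called 8308 genes, 4942 higher in females and 3366 higher in males.

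Among mutants, macrophage and lymphoid genes were higher in females, the lymphoid genes as in wild type. Inflammatory genes were higher in males, also as in wild type. Of 54 such genes 26 were higher in males and 4 in females (29 and 5 over the list alone). Of 47 macrophage genes 34 were higher in females and 1 in males (36 and 1 adjusted over the list alone), with Axl at 2.32 ± 0.237 and Mrc1 at 1.86 ± 0.205, the opposite sign to wild type. Of 40 B cell genes 29 and of 42 T and NK cell genes 35 were higher in females (32 and 37 over the list alone), against 0 and 1 in males, with Cd79b at 2.15 ± 0.188. Of 34 receptor genes 14 were higher in males and 1 in females (15 and 1 over the list alone), and Mpl was at -1.59 ± 0.302. The Y-linked genes Eif2s3y and Kdm5d were at -10.43 ± 0.405 and -10.25 ± 0.358. Apart from the sex-linked genes, the largest differences towards females were those of Syndig1l, A2m at 4.12 ± 0.620 and Klrb1a, an NK cell receptor gene, at 3.70 ± 0.686. BC018473 was at -5.27 ± 0.672, towards males, with 1 count summed over the mutant females and 57 over the males. Kdm5d also had 1 count there. A2m was at 7.85 ± 8.1 CPM (SD) in mutant females and Klrb1a had 5 summed counts in mutant males. Syndig1l had no count in the 4 mutant male libraries. This puts it at least 6.15-fold lower than in mutant females and at least 102-fold lower than in wild-type males, against a floor of 3 counts over the group that covers counting error only. edgeR called 4511 genes, 2544 higher in females and 1967 higher in males. The balance turned without mutant male replicate 1 (1648 and 2528), with DESeq2 size factors (2291 and 2337), with the DESeq2 Wald test (2528 and 2706) and with no filter on low counts (1803 and 2389). The call count was 7602 with limma-voom and sample quality weights.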

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

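The tests of the 3 patterns weighed below were chosen after the results had been seen, whereas the splits of the libraries were planned before. Some values stood apart from their group, by a gap to the nearest other library past Dixon's 95% critical value. This held in 8 of 52 groups, where chance gives about 1 in 20. Mpig6b in mutant female replicate 3 was at 3.86 CPM, against 1.78 to 1.88 CPM in the other 3 libraries. The share of macrophage genes was 1.2% in mutant male replicate 4 (others 1.3 to 1.32%) and 0.747% in wild-type female replicate 3 (others 1.26 to 1.34%). The share of B cell genes was 0.285% in wild-type male replicate 2 (others 0.174 to 0.181%). The share of basophil and mast cell genes was 1.42% in mutant female replicate 4 (others 1.04 to 1.08%) and 1.07% in wild-type male replicate 3 (others 0.992 to 1%). The share of osteoclast genes was 0.526% in mutant female replicate 3 (others 0.409 to 0.424%) and 0.366% in wild-type male replicate 1 (others 0.279 to 0.291%).

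The genotype effect differed between the sexes for 11 lists, by both camera with a preset correlation and fry on the interaction, and for 4875 genes by edgeR, of which Mpig6b and the 6 with the smallest p are given here. None of the lists passed with an estimated correlation. The median differences of log2 fold changes, females minus males, were -0.393 for megakaryocyte transcription factors, -2.563 for surface receptors, -0.783 for granules, -0.965 for the cytoskeleton, -0.555 for ITIM and Src family signalling, -1.2 for stem cell genes, 2.166 for macrophages, 1.236 for B cells, -2.288 for endothelial cells, -0.224 for glycolysis and -0.212 for oxidative phosphorylation. The gene differences were -3.07 for Mpig6b, 2.76 for Lgmn, 4.34 for Axl, 3.77 for Sdc3, 1.96 for Plxnb2, 3.76 for Slco2b1 and 2.68 for Vav2. As a percentage of Itga2b, Mpig6b was at 0.877 to 1.25% in mutant females and 9.99 to 11.5% in wild-type females. In males it was at 0.721 to 1.14% and 7.6 to 8.47%. On this scale its fall was similar in the sexes, so most of its difference of -3.07 went with that of Itga2b.

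Megakaryocyte genes were lower in mutant libraries. The highest-count genes taking up reads are argued against, since 33 of 34 receptor genes stayed lower with the 20 highest-count genes left out. A lower share of otherwise unchanged megakaryocytes would give every megakaryocyte gene 1 common fold. Of 47 genes, 14 needed a higher share than the lowest upper limit (0.125, Tubb1) allows, by more than 2 SE of the difference. By more than 2 SE, 2 exceeded the lower quartile of the limits (0.262) and 1 the median (0.396). With a simulated single share 0 of 145 genes did, but these genes were given no background. Subtracting mutant female values from them lowers the share they need, so this 0 is no reference for the counts found. All 3 bounds were tried after the results were seen and the background was assumed from mutant females, so the outcome depends on the bound, and a lower share cannot be told apart from lower expression per cell.

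Neutrophil genes were higher in mutant libraries. A lower share of megakaryocytes with all other cells in unchanged proportions would raise macrophage genes alike, but the neutrophil median exceeded the macrophage median by 3.61 in males. B cell genes did not rise there either (median -0.52). This rests on the wild-type males, for which a preparation apart cannot be excluded. In females the medians were 1.13 for neutrophil, 0.87 for T and NK cell, 0.65 for B cell and -0.56 for macrophage genes. These lists went in both directions, so in females it was not decided. The scaling of the libraries is argued against by a neutrophil median of at least 0.99 in the averaged comparison under the other scalings, and of 0.94 and 0.9 in males. A larger share of neutrophil cells, higher expression per cell and, in females at least, a lower share of megakaryocytes remain open.

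Macrophage genes were lower in mutant males. Dilution by the larger share of the neutrophil list would give a log2 fold change of -0.08, against a median of -2.69 and an upper quartile of -0.57. The share of all neutrophil transcripts was not measured, so dilution by these was not tested. For macrophage genes, a difference between the preparations of male and female samples that is the same in mutants and wild type is argued against. Their median log2 of female over male was -1.46 in wild type and 1.26 in mutants, with quartiles of 1.15 and 3.83 for the difference per gene. Some other lists kept their direction, and for them such a difference was not tested. T and NK cell genes had medians of 0.92 in wild type and 2.08 in mutants, and inflammatory genes -0.85 and -0.57. A preparation of the wild-type male samples apart from the other 3 groups cannot be told apart from a difference of that group, which had a macrophage share of 2.72%, since the labels give no preparation. It would leave the lower level in mutant males than in mutant females, and an effect of genotype or sex on macrophages stays open and untested.

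Relabelling the libraries gave the following counts as large as the real one, which is included. For genes these were 1 of 100 splits for the averaged comparison (highest other 9302), 1 of 35 for females (0) and 1 of 35 for males (0). They were 1 of 100 for the interaction (3304), 1 of 35 for sex in wild type (15) and 1 of 35 for sex in mutants (6). No other split drawn called as many genes, and 1 of 35 is the fewest that 35 splits allow. For the averaged comparison each sex was relabelled apart, and for the interaction each genotype. A split could therefore keep the real labels, or their mirror, in 1 sex or 1 genotype, and others keep them in part. Such splits still hold real differences, for genes and for lists, so the highest other counts there are no clean reference for chance. Relabelling cannot exclude a difference between animals or preparations that follows the groups, since the labels describe neither. For lists they were 33 of 100 for the averaged comparison (23), 1 of 35 for females (22), 12 of 35 for males (15) and 20 of 100 for the interaction (24). Chance cannot be excluded for the averaged, male and interaction list counts. In females no other split reached the real count, by a margin of 1 list only, 23 against 22. The real count is itself 22 without mutant female replicate 3 or wild-type female replicate 1, 2 or 3.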

How the results depend on the processing

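The alternatives were chosen before the data were examined, and no called gene or list changed direction. Medians near 0 changed sign with DESeq2 size factors, from -0.02 to 0.02 for cholesterol genes in the averaged comparison and from -0.02 to 0.01 for oxidative phosphorylation in males. The balance of higher and lower genes turned under some settings in females, in males and for sex in mutants. Counts of called genes stayed within 1.5 times of the stated ones in 143 cases, and 1 moved, the sex effect in mutants, with 7602 genes under limma-voom with sample quality weights against 4511. Without wild-type female replicate 3 it gave 6391 genes, and with only the 2 groups compared 6440. In males these settings gave 9227 and 9338 genes against 7694. That library enters both comparisons only through the shared fit, so it lowered their stated counts. A further cause was not tested. With an estimated correlation camera called 0 lists in each of the averaged, female, male and interaction comparisons, against 18, 23, 11 and 19, and fry called 12 lists for the interaction against 19. The cause was not tested. Leaving out 1 library gave 11736 to 12665 genes in the averaged comparison, 10795 to 12361 in females, 6220 to 9227 in males, 3862 to 6358 for the interaction, 7163 to 9300 for sex in wild type and 3343 to 6391 for sex in mutants, and 18 to 20, 22 to 23, 10 to 12 and 19 to 20 lists. Over all settings, named genes stayed on their side of the threshold in 10386 cases, passed it in 41 and lost it in 60. A count of 3 over 4 libraries, or 0.0278 CPM, is the floor that depth sets.

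With the replicate number as a replicate block, 11986 genes were called in the averaged comparison, 11712 in females, 7254 in males, 4462 for the interaction, 7796 for sex in wild type and 4087 for sex in mutants, and 20, 23, 11 and 20 lists. The residuals of 24 pairs with the same number correlated at -0.28 to 0.27, 3 above 0.1, and 3 of 16 libraries correlated best with their own number, so the numbers do not pair the samples.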

Other observations

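Genes next to Mpig6b were also lower in the mutants. These were examined after the values had been seen. The labels do not describe the mutant allele, and whether it acts on these neighbours directly was not tested. In the averaged comparison Ly6g6c was at -3.96 ± 0.361, Ly6g6d at -3.84 ± 0.263, Ly6g6e at -3.78 ± 0.331 and Ly6g6f at -3.95 ± 0.252 (log2, SE), and Ddah2 was at -1.30 ± 0.167 and Abhd16a at -0.49 ± 0.090. Clic1 was slightly higher, at 0.17 ± 0.048, while Msh5 (adjusted p = 0.357) and Vwa7 (adjusted p = 0.411) did not pass in edgeR. The Ly6g6 genes fell more in females than in males, with Ly6g6f at -5.68 and -2.21 and Ly6g6d at -5.44 and -2.24. Receptor genes did so too, with medians of -3.74 and -1.22, so these falls went with those of megakaryocyte genes. By the coordinates Ly6g6d overlaps Ly6g6e and Ly6g6f, so their counts are uncertain.

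Ptpn21, a tyrosine phosphatase gene on chromosome 12, had the largest increase at any level among the genes ranked. These were called protein-coding genes with every mutant library above every wild-type library. Ptpn21 lay in the averaged comparison. It was at 4.77 ± 0.88 CPM (SD, n = 4) in mutant females and 4.54 ± 0.48 CPM in mutant males, against 0.116 ± 0.087 and 0.223 ± 0.039 CPM in wild type, a log2 fold change of 4.80 ± 0.193 (SE). It fell below the expression limit of the rule for named genes and was picked out after its value was seen.

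Of the genes called in both sexes, 112 were lower in females and higher in males and 155 the reverse. Slamf6, a lymphocyte receptor gene, was at 0.53 in females and -2.47 in males, and Steap4, a metalloreductase gene, at -1.32 and 1.69. These were picked by the smallest p of the interaction, after the values were seen.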
